A study of Mus musculus with 12 samples.

How the data were processed

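RNA was measured in 12 libraries of isolated islets from C57BL/6J mice, 3 libraries in each of 4 treatment groups. The islets were cultured for 24 hours with vehicle, with ML351 at 10 µM, with a cytokine mixture, or with the cytokine mixture and ML351 together. The mixture held interleukin-1β at 5 ng/ml, tumour necrosis factor α at 10 ng/ml and interferon γ at 100 ng/ml. ML351 is an inhibitor of 12/15-lipoxygenase, an enzyme that oxygenates polyunsaturated fatty acids. Per the labels' protocols, libraries were made with a SMARTSeq v4 kit, which amplifies full-length cDNA and does not record the strand. Without strand, reads of a gene and of an antisense or overlapping partner cannot be told apart.

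The deposited values are counts of reads per gene symbol, whole numbers in 1 column per library, not normalized and not pooled. The submitters' processing notes name FastQC, STAR, featureCounts, Subread and DESeq2, without versions or roles, and the mouse build mm10. The gene annotation and any filter on low counts are not given in the sources used here. Each of the 14089 genes reached at least 0.503 CPM (counts scaled to the library total) in 3 or more libraries, and 13543 had a count in each of the 12. Totals ran from 20208286 to 27193026 counts per library. Counting error is small next to the spread between libraries except for genes near the lower end. Coordinates were taken from GENCODE M21 on GRCm38, the same assembly as mm10, in which 13589 of the symbols were found. With RefSeq symbols and synonyms 14057 were matched, and renamed members of gene lists were looked up that way.

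Groups were taken from the treatment named for each sample. Nothing in the labels says whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The 3 libraries of each group were compared with each other before averaging, and in no pair did the counts match within sampling noise.

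Changes in expression were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (robust glmQLFit, glmQLFTest), with TMM scaling, filterByExpr by group, and all 12 libraries in one model with a mean per group. The filter removed no gene. Contrasts were made of these means: cytokines against vehicle, ML351 against vehicle, cytokines plus ML351 against cytokines, cytokines plus ML351 against ML351, the ML351 effect averaged over both backgrounds, and the interaction of both treatments. In this model adjusted p-values are Benjamini-Hochberg values over the 14089 genes within a contrast, and a gene was called at 0.05. Fold changes are log2 values from edgeR. Their standard errors (SE) were computed as the size of the log2 fold change divided by the square root of F. CPM use the library total multiplied by the TMM factor, except in the filters and in the 0.503 CPM given above, which use the total alone. Group values of CPM are given as mean ± SD over 3 libraries.

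Gene lists, 31 in number, were fixed: those of cell type markers (beta, alpha, delta, PP, acinar, ductal, endothelial, stellate and fibroblast, macrophage, lymphocyte, Schwann cells) and those of pathways (interferon response, MHC class I, MHC class II, NF-κB targets, chemokines, exocytosis, NRF2 targets, antioxidant enzymes, NADPH oxidase, eicosanoid enzymes, ER stress, apoptosis, AHR and xenobiotic metabolism, oxidative phosphorylation, glycolysis, cholesterol synthesis, fatty acid synthesis, cell cycle, mitochondrial transcripts, immediate early and stress genes). Of their 574 members 519 were tested. The lists with 3 or more tested members, 29 in number, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 29 lists of a contrast. The mitochondrial transcript list had 0 tested of 13 members and the lymphocyte list 2 of 14, and neither was tested as a list. Camera compares a list with the other genes. It was run again with a correlation estimated per list, and fry was run for the direction and for change in either direction. Counts of called list members are given with p adjusted over all genes and adjusted over the list alone.

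Genes were named by a rule. For each contrast other than the interaction it took called genes with an average log2 CPM of at least 3 and no overlap between the groups compared (within each background for the averaged contrast), and of these the 8 largest rises and the 8 largest falls, passing over unnamed gene models, pseudogenes ending in -ps, Xist and Y-linked genes. The interaction took the 5 smallest p-values. Up to 4 members of each list with the smallest p in a contrast were added, as were Alox15, Alox12, Alox5, Ins1, Ins2, Pdx1, Nos2, Cxcl10, Gpx1, Sod1, Sod2, Cat, Nfe2l2, Hmox1, Nqo1, Txnip and Ddit3. Fewer than 5 called genes would all have been named. Other genes are named as chosen after their values were seen. Alox15 and Alox5 are not analysed here. Some genes that the rule selects are not reported here.

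The groups, tests, lists, naming rule and the first set of alternatives were fixed before the data were examined. These alternatives were DESeq2 size factors in edgeR, scaling without the 20 most abundant genes, no filter on low counts, a stricter filter (1 CPM in at least 6 libraries), the Wald test of DESeq2 1.42.0, limma-voom, a model of only the groups compared, the replicate number as a block, and each library left out in turn. The Wald test of DESeq2 gave an adjusted p to fewer genes, so its counts of calls are not over the same set as those of edgeR. These were 9716 genes for ML351 against vehicle and 12716 for cytokines plus ML351 against cytokines. They were 11898 for the averaged contrast and 3709 for the interaction. The list test was repeated with an estimated correlation, fry, no filter, the block, DESeq2 size factors and each library left out. A covariate of acinar RNA (the mean log2 CPM of the acinar list without Bhlha15) and the removal of both libraries at the ends of the second principal component were added after the data had been seen. The tests were tried on simulated counts with the real library sizes and the means of the vehicle and cytokine groups. In these, 200 of 14089 genes were changed, all with a mean of at least 20 counts. For ML351 against vehicle, 13.4% of genes changed 1.25-fold, 47.8% of those changed 1.5-fold and 84.8% of those changed 2-fold were recovered. For cytokines plus ML351 against cytokines the shares were 19.4%, 65.7% and 83.3%, for the averaged contrast 43.3%, 79.1% and 89.4%, and for the interaction 7.46%, 41.8% and 50%. For cytokines against vehicle they were 17.9%, 61.2% and 78.8%, and for cytokines plus ML351 against ML351 14.9%, 62.7% and 80.3%. In both these runs all groups started from the vehicle means, so the shares do not describe contrasts in which most genes are called. Unchanged genes called numbered 5 for ML351 against vehicle, 6 for cytokines plus ML351 against cytokines, 9 for the averaged contrast and 5 for the interaction. They numbered 4 for cytokines against vehicle and 8 for cytokines plus ML351 against ML351.

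Genes of families with near-identical copies (Gbp, Tgtp, Ly6, H2 and Try genes) can share reads, and their single values are uncertain. Clec7a and Cxcl11 are annotated in GENCODE M21 as polymorphic pseudogenes.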

Results

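Transcript levels of cultured mouse islets were measured by RNA sequencing under 4 conditions, with 3 libraries in each. The islets received vehicle, ML351 alone, a mixture of pro-inflammatory cytokines, or the mixture together with ML351 (called the combination here), and were collected after 24 hours. The design addresses how inhibition of 12/15-lipoxygenase alters the islet response to inflammation, in a study of oxidative stress in β cells. Library totals were 23519151, 20664596 and 22331264 counts for vehicle replicates 1, 2 and 4, and 21780484, 27193026 and 24069415 counts for ML351 replicates 1, 2 and 3. They were 25027095, 21225028 and 21435657 counts for cytokine replicates 1, 3 and 4, and 20732505, 21855322 and 20208286 counts for combination replicates 1, 2 and 4. A single gene, Ins2, took 19.9% to 25.5% of the counts of a library and Ins1 took 4.18% to 7.98%.

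Cytokine treatment separated the libraries on the first principal component, which held 82.3% of the variance. All 6 libraries without cytokines lay between -87.9 and -71.8 on it, and all 6 with cytokines between 74.9 and 85. The second component held 5.14%. At its ends lay ML351 replicate 1 (-36.8), with the other ML351 libraries at -0.6 and 10.2, and cytokine replicate 1 (42.3), with the other cytokine libraries at -3.5 and 20.1. The combination libraries lay at -28.7, -15.6 and -9.9, and the vehicle libraries between 3.7 and 10.6. RNA of acinar cells, the enzyme-secreting cells of the exocrine pancreas, varied between libraries. The summed CPM of the acinar markers was 683, 442 and 172 with vehicle, 236, 289 and 105 with ML351, 44.3, 660 and 955 with cytokines, and 1390, 1640 and 1110 with the combination, in the replicate order given above.

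**Figure D1:**
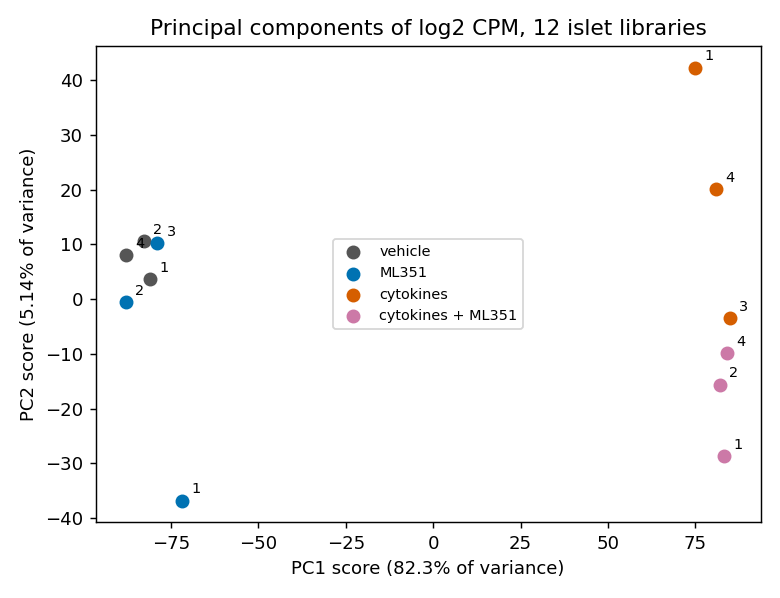
Principal components 1 and 2 of the log2 CPM of the 12 libraries, with the share of variance on each axis and 1 point per library, coloured by group. Libraries with cytokines lie to one side of component 1 (82.3% of the variance) and libraries without to the other, and ML351 replicate 1 and cytokine replicate 1 lie at the ends of component 2 (5.14%).

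Cytokines against vehicle asked how islet transcripts change in an inflammatory environment, and immune signalling genes showed the largest rises. Nos2 (chromosome 11, 78920787 to 78960254, GRCm38), which encodes inducible nitric oxide synthase, rose from 3.88 ± 0.952 CPM with vehicle to 1230 ± 51.5 CPM with cytokines (SD, n = 3 each; log2 fold change 8.29, SE 0.13, edgeR adjusted p = 2.3e-17). The chemokine gene Cxcl10 (chromosome 5, 92346638 to 92348889) rose from 4 ± 0.897 to 1120 ± 166 CPM (8.11, SE 0.22, adjusted p = 1.2e-10). The other largest rises under the naming rule were of Gbp10 (8.47), Ubd (8.34), Cxcl11 (8.32), Ly6i (8.27), Iigp1 (8.22), Zbp1 (8.21) and Cxcl9 (8.21). Ly6i had 4 counts in the vehicle libraries together, and its vehicle level was 0.306% of the cytokine level (0.0833% to 0.783%, 95% Poisson interval for counting error only).

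Gene groups of immune signalling rose together with cytokines. All 32 measured members of the interferon response list rose, with a median log2 fold change of 5.49 (camera adjusted p = 5.9e-18, and adjusted p = 0.018 with an estimated correlation). Among them were the guanylate-binding protein gene Gbp2 (8.05), Igtp (5.77) and Cd274, which encodes PD-L1 (5.65). All 16 members of the MHC class I list rose (median 3.48, camera adjusted p = 1.7e-11, and 0.0087 with an estimated correlation), including Tap1 (5.46), Psmb8 (4.78), B2m (4.48) and Tapbpl (3.14). Of 27 NF-κB targets 26 rose and 0 fell (median 3.41, camera adjusted p = 9.8e-13, and 0.046 with an estimated correlation), with Birc3 at 3.56 and Tnip1 at 3.09. Of 18 chemokine genes 15 rose, while Cxcl12 (-1.07) and Cx3cl1 (-0.52) fell (median 4.53, camera adjusted p = 3.5e-06, but adjusted p = 0.057 with an estimated correlation). Ccl2 (7.69), and Il6 (6.73) of the NF-κB targets, were picked after their values were seen. All 7 MHC class II genes rose (median 3.33, camera adjusted p = 9.9e-05, adjusted p = 0.15 with an estimated correlation), among them Ciita (6.45), Cd74 (4.23) and H2-Aa (3.33).

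Genes of endocrine identity were lower with cytokines. Pdx1 (chromosome 5, 147269959 to 147275848), a transcription factor of β cells, fell from 70.5 ± 3.86 to 6.87 ± 0.621 CPM (SD, n = 3; log2 fold change -3.35, SE 0.11, adjusted p = 4.8e-14). Gcg (chromosome 2, 62474530 to 62483650), which encodes glucagon, fell from 36100 ± 2040 to 885 ± 346 CPM (-5.35, SE 0.43, adjusted p = 3.7e-06). Ins1 (chromosome 19, 52264297 to 52265476) fell from 76900 to 50600 CPM (-0.60, SE 0.1, adjusted p = 5.4e-05), while Ins2 (chromosome 7, 142678656 to 142743381) was at 243000 and 232000 CPM (-0.07, SE 0.096, adjusted p = 0.54). Of 30 β-cell genes 26 fell and 1, Chgb (0.81), rose (median -1.85, camera adjusted p = 1.6e-09, but adjusted p = 0.12 with an estimated correlation). Members that fell included Ucn3 (-5.03), Prlr (-3.37) and Pax6 (-1.85). Mafa (-4.63; 165 ± 10.5 to 6.66 ± 1.01 CPM) and Slc2a2 (-3.95), both chosen after their values were seen, fell as well, and Iapp was at -0.01 (adjusted p = 0.91). All 10 α-cell genes fell (median -4.01, camera adjusted p = 2.9e-05, adjusted p = 0.14 with an estimated correlation), with Irx2 at -4.17. All 5 δ-cell genes fell (median -2.77, camera adjusted p = 0.0031, adjusted p = 0.12 with an estimated correlation), with Sst at -3.73, Casr at -2.77 and Hhex at -2.76. All 4 PP-cell genes fell (median -2.40, camera adjusted p = 0.018, adjusted p = 0.14 with an estimated correlation), with Pyy at -5.18 and Ppy at -3.05. Among the largest falls by the naming rule were those of Sfrp5 (-8.26; 63.1 to 0.203 CPM), Edn3 (-8.01), Hapln1 (-6.40), Oxtr (-6.37), Pdk4 (-5.67), Kctd12b (-5.35) and Gcg.

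Several genes that respond to oxidative and endoplasmic reticulum (ER) stress rose with cytokines. Sod2, the mitochondrial superoxide dismutase, rose from 96 to 914 CPM (log2 fold change 3.25, SE 0.067, adjusted p = 8.5e-17, n = 3 each). Gpx1, a glutathione peroxidase, rose from 99.9 to 421 CPM (2.07, SE 0.083, adjusted p = 7.5e-13), and the heme oxygenase gene Hmox1 rose from 59.3 to 906 CPM (3.93, SE 0.11, adjusted p = 7.7e-13). Ddit3, a transcription factor of the stress response, rose from 19.3 to 501 CPM (4.69, SE 0.074, adjusted p = 3.2e-18). Of 28 antioxidant enzymes 18 rose and 7 fell (median 0.47, camera adjusted p = 0.0082, adjusted p = 0.21 with an estimated correlation). Mt2 (3.75), Cat (1.46), Gsr (1.18) and Sod1 (0.91) rose, and Txnip, which binds thioredoxin and is in no list, fell (-0.73). Of 25 NRF2 targets 16 rose and 6 fell (median 0.56, camera adjusted p = 0.0068, adjusted p = 0.29 with an estimated correlation), among the risen ones Fth1 (2.30), Ftl1 (1.72) and Gclm (1.66). Nfe2l2, which encodes NRF2, rose (1.15). Nqo1 rose by 0.42 (adjusted p = 0.041), a call that 9 of 22 alternatives ended (adjusted p 0.000144 to 0.125), including the removal of vehicle replicate 1, 2 or 4, ML351 replicate 2 or 3, or cytokine replicate 3 or 4. Of 10 NADPH oxidase genes 5 rose (median 1.02, camera adjusted p = 0.036, adjusted p = 0.14 with an estimated correlation), among them Cybb (2.35), Cyba (1.95) and Rac1 (1.02). Of 28 ER stress genes 13 rose and 11 fell (median 0.07, camera adjusted p = 0.23), with Trib3 (3.19) and Ppp1r15a (3.24) risen and Atp2a2 (-1.40) fallen.

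Alox12 (chromosome 11, 70241457 to 70255353), which encodes the platelet-type 12-lipoxygenase, rose with cytokines from 0.368 ± 0.197 to 14.1 ± 1.76 CPM (SD, n = 3; log2 fold change 5.22, SE 0.25, adjusted p = 4.8e-12). Of 19 eicosanoid enzyme genes 9 rose and 3 fell (median 0.59, camera adjusted p = 0.09). Ptgs2 (4.95, chosen after its value was seen) and Ptges2 (0.79) rose, and Pla2g6 (-1.58) and Alox5ap (-1.84) fell. Of 27 apoptosis genes 21 rose and 4 fell (median 0.87, camera adjusted p = 9.9e-05, but adjusted p = 0.057 with an estimated correlation), with Fas at 5.99, Casp1 at 5.08, Tnfsf10 at 3.26 and Bid at 2.37. Of 19 glycolysis genes 17 rose and 1, Pfkm (-1.65), fell (median 1.29, camera adjusted p = 2.9e-05, adjusted p = 0.24 with an estimated correlation), with Pfkfb3 at 4.35, Gapdh at 1.55 and Aldoa at 1.39. Oxidative phosphorylation genes moved both ways, 19 of 30 up and 8 down (median 0.32, camera adjusted p = 0.094), from Ndufa4 (-1.44) to Atp5b (0.70). Of 20 exocytosis genes 13 fell and 5 rose (median -0.49, camera adjusted p = 0.043, adjusted p = 0.17 with an estimated correlation), with Cplx2 (-2.59), Rab3a (-2.11) and Rab27a (-1.54) fallen. Exocytosis was not called without cytokine replicate 3 (adjusted p = 0.057) or 4 (0.053), or with the replicate block (0.053). Of 22 cholesterol synthesis genes 13 fell and 4 rose (median -0.53, camera adjusted p = 0.043, adjusted p = 0.29 with an estimated correlation), among them Insig1 (-0.99) and the risen Fdps (1.47). Without vehicle replicate 1 the adjusted p of cholesterol synthesis was 0.065, and without cytokine replicate 1 it was 0.056. Of 16 fatty acid synthesis genes 10 fell and 3 rose (median -0.62, camera adjusted p = 0.086), with Fasn (-1.70) and Acly (-1.63) fallen and Acsl4 (0.94) risen.

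Cell cycle genes fell in 19 of 22 cases and rose in 1 (median -1.92, camera adjusted p = 0.0043, adjusted p = 0.29 with an estimated correlation), with Ccna2 at -3.30, Top2a at -3.12 and Mcm5 at -1.07. Of 14 immediate early and stress genes 13 rose (median 1.55, camera adjusted p = 0.00018, adjusted p = 0.15 with an estimated correlation), with Jun at 2.77 and Dusp1 at 1.92. Of 13 AHR and xenobiotic genes 7 rose and 1 fell (median 0.71, camera adjusted p = 0.2), with Abcb1a (3.02), Tiparp (1.27) and Por (0.39) risen and Ugt1a6a (-1.88) fallen, while Cyp1a1 was at -0.78 (adjusted p = 0.082). Markers of other cell types moved in both directions. All 11 endothelial markers fell (median -2.26, camera adjusted p = 0.00053, adjusted p = 0.15 with an estimated correlation), among them Kdr (-3.12), Plvap (-2.88) and Flt1 (-2.67). Of 15 macrophage markers 9 rose and 1, Lyz2 (-0.49), fell (median 0.96, camera adjusted p = 0.036, adjusted p = 0.24 with an estimated correlation), with Cd68 at 2.89 and C1qb at 1.38. Of 14 stellate and fibroblast markers 9 fell and 1 rose (median -1.54, camera adjusted p = 0.17), with Acta2 at -2.30 and Des at -2.11. Of 9 ductal markers 5 rose and 1 fell (median 1.84, camera adjusted p = 0.12), with Spp1 at 1.90, Krt7 at 0.78 and Epcam at 0.77. Of 7 Schwann cell markers 1, Cnp (1.39), rose and 3 fell (median -0.30, camera adjusted p = 0.67), among them Ncam1 (-1.06). Of 19 acinar markers 0 rose by edgeR and 1, the transcription factor gene Bhlha15 (-3.27), fell. The acinar median was 0.47 and the mean 0.27, but camera ranked the list downwards (adjusted p = 0.71). The lymphocyte genes measured were Lck (1.93, adjusted p = 1.3e-09) and Cd79a (-0.78, adjusted p = 0.015), and the mitochondrial transcript list had 0 members to test.

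In all, edgeR called 10209 of 14089 genes (72.5%) with cytokines against vehicle, 4969 higher and 5240 lower, of which 2098 rose and 2434 fell more than 2-fold. The CPM of both groups did not overlap for 76.6% of genes, against 10% by chance. Camera called 20 of 29 lists, 12 up and 8 down, of which 3 (interferon response, MHC class I and NF-κB targets) held with an estimated correlation. List members were called 433 times over all genes and 431 times when adjusted over the list alone, and the number was the same in 26 of 29 lists. The exceptions were 6 rather than 8 AHR and xenobiotic genes, 4 rather than 5 NADPH oxidase genes and 25 rather than 24 ER stress genes.

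**Figure D2:**
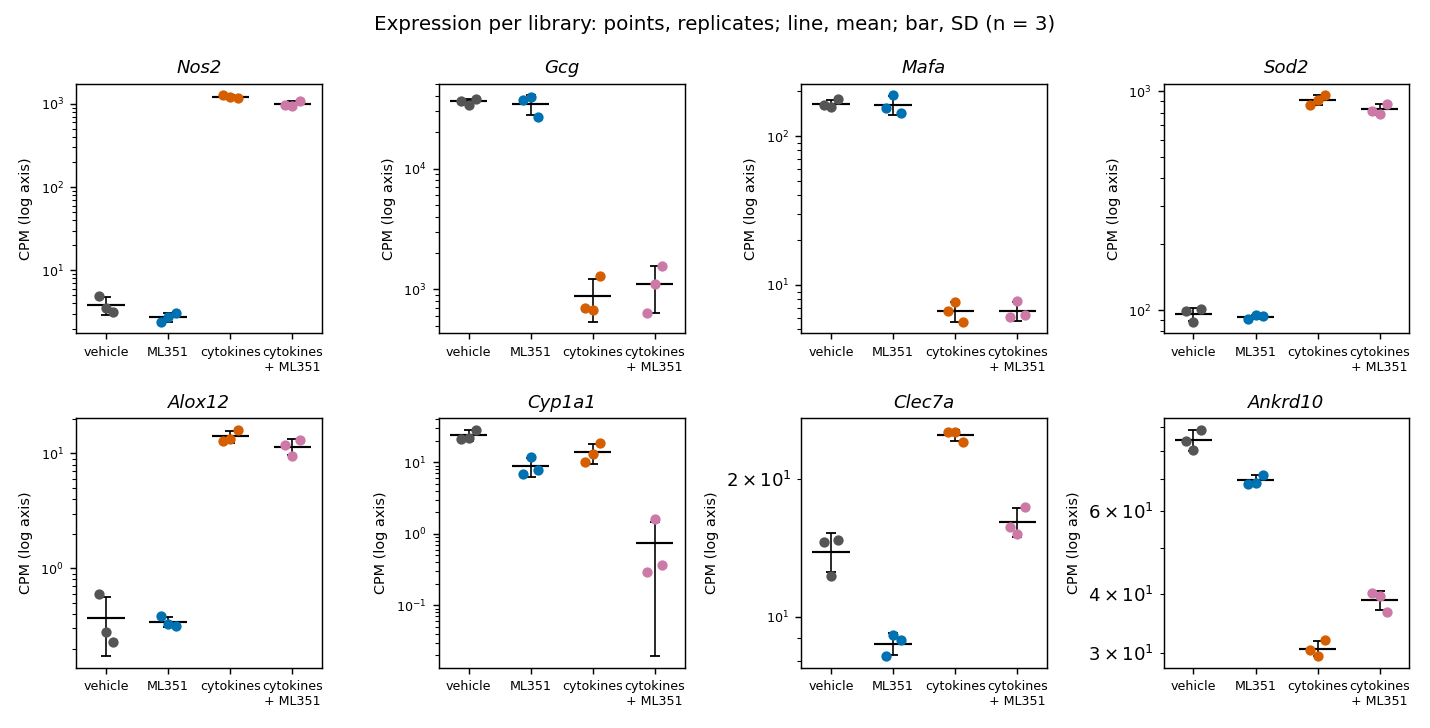
CPM of 8 genes per library on a log axis, by group, with points for replicates, a line for the group mean and a bar for the SD (n = 3). Nos2, Sod2 and Alox12 lie higher and Gcg and Mafa lower in both groups with cytokines, Cyp1a1 and Clec7a are lower with ML351 in the averaged contrast (log2 fold change -2.79 and -0.65), and Ankrd10 shows the 1 called interaction (0.62).

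**Figure D3:**
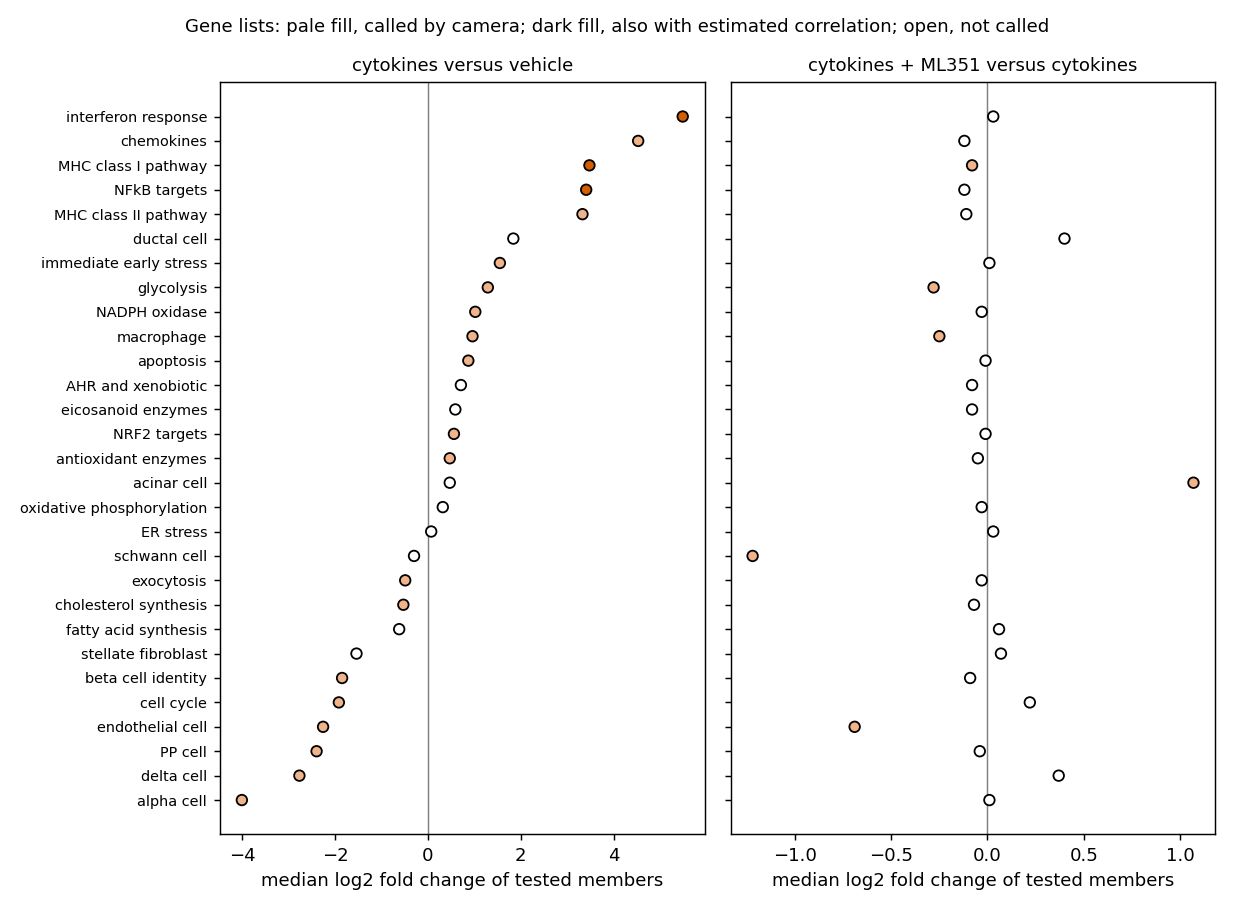
Median log2 fold change of 29 gene lists, on the left for cytokines against vehicle and on the right for the combination against cytokines. Pale fill marks lists called by camera, dark fill those also called with an estimated correlation (3 on the left, 0 on the right) and open symbols lists not called.

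ML351 against vehicle asked what the inhibitor does without cytokines, and edgeR called 5 genes, with 1265 at an unadjusted p under 0.05. Xpo1, a nuclear export receptor, rose from 54.6 ± 1.29 to 69.6 ± 0.965 CPM (SD, n = 3; log2 fold change 0.35, SE 0.057, edgeR adjusted p = 0.042). The lysosomal channel gene Mcoln1 rose by 0.34 (SE 0.056). Clec7a (chromosome 6, 129461591 to 129472779), which encodes the β-glucan receptor of macrophages, fell from 13.9 ± 1.36 to 8.74 ± 0.476 CPM (-0.67, SE 0.1). The copper transporter gene Atp7a fell by 0.43 (SE 0.069), and Enpp2, which encodes autotaxin, fell by 0.40 (SE 0.066). The adjusted p was 0.042 for each of these 5 genes. Cyp1a1, a xenobiotic-metabolising enzyme, was at 23.9 ± 4.11 CPM with vehicle and 8.87 ± 2.55 CPM with ML351 (-1.43, adjusted p = 0.27). Values of other genes of interest were Nos2 -0.51 (adjusted p = 0.29), Nfe2l2 -0.29 (0.17), Ddit3 0.24 (0.27), Ins1 -0.16 (0.7), Ins2 -0.17 (0.66), Pdx1 -0.13 (0.76), Sod2 -0.04 (0.91) and Alox12 -0.13 (0.97).

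Of 15 macrophage markers 0 were called over all genes and 8 were lower when adjusted over the list alone with ML351 (median -0.42, camera adjusted p = 1.7e-10, and 0.029 with an estimated correlation). C1qc stood at -0.57 (adjusted p = 0.071 over all genes), C1qa at -0.39 (0.083), Tyrobp at -0.60 (0.094) and Adgre1 at -0.80 (0.18). Of 7 MHC class II genes 3 were lower adjusted over the list alone (median -0.64, camera adjusted p = 2.5e-07, adjusted p = 0.16 with an estimated correlation), with H2-Aa at -0.78 (0.12). Of 28 ER stress genes 14 were higher adjusted over the list alone (median 0.17, camera adjusted p = 1.7e-10, adjusted p = 0.16 with an estimated correlation), among them the chaperone genes Hspa5 (0.24), Calr (0.22), Pdia6 (0.25) and Dnajb11 (0.31). Of 4 PP-cell genes 1, Fxyd6, was lower adjusted over the list alone (median -0.37, camera adjusted p = 0.0048, adjusted p = 0.14 with an estimated correlation). Ppy was at 2320 and 2420 CPM in ML351 replicates 1 and 2, at 7110 in replicate 3, and at 7550, 8000 and 8830 with vehicle. Of 10 NADPH oxidase genes 2 were lower adjusted over the list alone. Their median was -0.16 and their mean 0.70, and camera ranked the list down (adjusted p = 0.011, adjusted p = 0.14 with an estimated correlation). Duox2, whose level varied between ML351 libraries (0.221 ± 0.168 to 9.8 ± 16.2 CPM), was at 5.39 with an SE of 2.8. Of 13 AHR and xenobiotic genes 5 passed adjusted over the list alone, 1 higher and 4 lower (median -0.10, camera adjusted p = 0.0061, adjusted p = 0.30 with an estimated correlation). Camera also called β-cell genes (median -0.08, adjusted p = 0.0088, adjusted p = 0.73 with an estimated correlation), chemokines (-0.29, 0.0088, and 0.30 with an estimated correlation) and acinar markers (-1.12, 0.044, and 0.86 with an estimated correlation), with 0 members of each called by edgeR adjusted over the list alone.

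Camera called 9 of 29 lists for ML351 against vehicle, 1 up and 8 down, of which the macrophage list alone held with an estimated correlation. Without single libraries several were not called. The β-cell list had an adjusted p of 0.17 without vehicle replicate 4, 0.062 without ML351 replicate 1 and 0.18 without ML351 replicate 3. The acinar list had 0.48 and 0.2 without vehicle replicates 1 and 2, 0.56 without ML351 replicate 3, 0.058 without cytokine replicate 3, and 0.094, 0.069 and 0.11 without combination replicates 1, 2 and 4. Without ML351 replicate 2 the values were 0.29 for chemokines and 0.053 for both the NADPH oxidase and the AHR and xenobiotic lists. With the replicate block camera called 10 lists, of which 7 were among the 9. Median, mean and test also differed in sign for exocytosis (-0.01, 0.01, up), fatty acid synthesis (0.01, -0.01, up) and MHC class I genes (0, -0.03, down), all not called. List members were called 44 times when adjusted over the list alone and 0 times over all genes by edgeR.

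Of the 5 genes called by edgeR for ML351 against vehicle 2 were higher and 3 lower, while DESeq2 called 110 and limma-voom 7. The CPM of both groups did not overlap for 15.9% of genes, against 10% by chance. The count rests on single libraries: 0 were called without vehicle replicate 1 or 4, ML351 replicate 1, or cytokine replicate 1 or 4, 1 without vehicle replicate 2 or cytokine replicate 3, 2 without combination replicate 1, 12 without ML351 replicate 3 or combination replicate 2, 15 without combination replicate 4, and 17 without ML351 replicate 2. With the replicate block 0 were called, and 0 without both libraries at the ends of the second component. The 5 calls were lost in 10 (Clec7a) to 14 (Mcoln1, Atp7a) of 22 alternatives, with adjusted p from 6.12e-06 (Enpp2) to 0.302 (Mcoln1).

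The combination against cytokines asked whether ML351 alters the cytokine-treated state. Cyp1a1 (chromosome 9, 57687928 to 57703824) fell from 13.9 ± 4.37 CPM with cytokines to 0.749 ± 0.729 CPM with the combination (SD, n = 3; log2 fold change -4.15, SE 0.51, edgeR adjusted p = 0.012). Clec7a fell from 24.9 to 16.1 CPM (-0.63, SE 0.096, adjusted p = 0.0087), and the cytidine deaminase gene Cda fell from 30.6 to 18.5 CPM (-0.73, SE 0.093, adjusted p = 0.0028). Nr4a1 (chromosome 15, 101254269 to 101274795), an orphan nuclear receptor induced by stimulation, rose from 4.33 ± 1.08 to 13 ± 1.88 CPM (1.58, SE 0.31, adjusted p = 0.04). The other largest rises were of Dbpht2 (0.94), Nr4a2 (0.91), Wdr90 (0.86), Atad2 (0.73), Ppl (0.68), Arl15 (0.61) and Sec16b (0.57), with adjusted p from 0.027 to 0.05. The other largest falls were of Plvap (-1.09), Kdr (-0.95), Blnk (-0.66), Eng (-0.66) and Laptm5 (-0.63), with adjusted p from 0.013 to 0.05. Other genes fixed for every comparison were not called. Nos2 was at 1230 and 998 CPM (-0.30, SE 0.084, adjusted p = 0.1), Cxcl10 at 0.07 (0.87), Hmox1 at 0.00 (1), Sod2 at -0.14 (0.27), Gpx1 at -0.06 (0.78), Sod1 at -0.19 (0.18), Ddit3 at -0.09 (0.5), Alox12 at -0.30 (0.43), Nfe2l2 at -0.25 (0.07), Pdx1 at -0.07 (0.85), Ins1 at -0.10 (0.66) and Ins2 at -0.10 (0.67).

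Endothelial markers were lower with the combination than with cytokines. Of 11, 4 fell over all genes (Plvap, Kdr, Eng and Cdh5, the last at -1.35) and 7 adjusted over the list alone (median -0.69, camera adjusted p = 1.9e-07, adjusted p = 0.25 with an estimated correlation). Of 19 glycolysis genes 2, Pgam1 (-0.36) and Pkm (-0.27), fell and 9 were called adjusted over the list alone (median -0.28, camera adjusted p = 6.1e-07, adjusted p = 0.60 with an estimated correlation). Of 15 macrophage markers 1, C1qc (-0.48), fell and 2 were called adjusted over the list alone (median -0.25, camera adjusted p = 0.00037, adjusted p = 0.25 with an estimated correlation). Of 19 acinar markers 1, Bhlha15 (0.57), rose by either adjustment (median 1.07, camera adjusted p = 8e-06, adjusted p = 0.79 with an estimated correlation). The summed acinar CPM, which leaves out Bhlha15, was 44.3, 660 and 955 in the cytokine libraries and 1390, 1640 and 1110 in the combination libraries. Bhlha15 did not follow this sum. It was at 89.9 ± 2.14 CPM with vehicle, where the sum was 683, 442 and 172, and at 9.3 ± 2.05 CPM with cytokines. Its call is therefore no evidence on the amount of acinar RNA. MHC class I genes (0 over all genes by edgeR, 2 adjusted over the list alone, median -0.08, camera adjusted p = 0.016) and Schwann cell markers (0 and 2, median -1.22, camera adjusted p = 0.016) were also called, and had an adjusted p of 0.35 and 0.66 with an estimated correlation. The MHC class I list was not called without cytokine replicate 4 (adjusted p = 0.058) or combination replicate 4 (0.088), nor the Schwann cell list without combination replicate 1 (0.098). Of single list members, the chaperone gene Hspa5 (0.29), the δ-cell gene Hhex (1.07) and the antiviral gene Rsad2 (0.36) rose, and Cplx2 (-0.49) and Krt7 (-0.23) fell, with adjusted p from 0.027 to 0.05.

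Camera called 6 of 29 lists for the combination against cytokines, 1 up and 5 down, and 0 with an estimated correlation, while fry called the endothelial (0.016) and macrophage (0.033) lists and found change in either direction in 14. Without combination replicate 2 camera called 11 lists. Median, mean and test differed in sign for apoptosis (-0.01, 0.07, down), NADPH oxidase (-0.03, 0.24, down), stellate and fibroblast (0.07, 0.24, down), α-cell (0.01, 0, down), eicosanoid (-0.08, 0.01, down), NRF2 (-0.01, 0.09, down) and PP-cell genes (-0.04, -0.02, up), all not called. Members were called 14 times over all genes and 47 times adjusted over the list alone.

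In all, edgeR called 202 genes (1.43%) for the combination against cytokines, 91 higher and 111 lower, of which 11 and 12 changed more than 2-fold, and the CPM did not overlap for 20.4% of genes, against 10% by chance. With DESeq2 size factors the split was 71 higher and 142 lower, and it turned to 45 higher and 29 lower without cytokine replicate 3, against 32 higher and 104 lower without combination replicate 1. The count was 90, 114 and 125 without vehicle replicates 1, 2 and 4, 74, 74 and 54 without cytokine replicates 1, 3 and 4, and 80 without combination replicate 2. It was 527 with DESeq2, 53 with the replicate block, 76 without both libraries at the ends of the second component, 60 of them among the 202, and 36 with the acinar covariate. Of 26 called genes named by the rule, Cda (highest adjusted p over 22 alternatives 0.0325) and Clec7a (0.0422) were called throughout, and 24 were lost at least once. Cyp1a1 was lost in 1 alternative (adjusted p 6.7e-11 to 0.0863), Blnk in 3, Plvap, Cplx2 and Dbpht2 in 5, Eng and Pgam1 in 6, Wdr90 in 7, Hspa5, Hhex and Ppl in 8, Nr4a1 and C1qc in 9, and Pkm in 10. Lost in 11 or more were Atad2 (11), Bhlha15 (12), Krt7 and Sec16b (13), Nr4a2 (14), Cdh5, Laptm5 and Rsad2 (15), Kdr (16) and Arl15 (17).

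The combination against ML351 gave the cytokine response in the presence of the inhibitor. Nos2 rose from 2.74 ± 0.325 to 998 ± 81.4 CPM (SD, n = 3; log2 fold change 8.50, SE 0.13, edgeR adjusted p = 2.4e-17). Cxcl11 rose by 9.43 (SE 0.2, adjusted p = 1.4e-16) from 6 counts in the ML351 libraries together. Ly6i had 2 counts in the ML351 libraries, and its level there was 0.13% of that with the combination (0.0157% to 0.468%, 95% Poisson interval). The other largest rises were of Ubd (8.97), Gbp10 (8.73), Cxcl9 (8.58), Gbp4 (8.40) and Tgtp1 (8.34). Gcg fell from 34100 to 1100 CPM (-4.96, SE 0.42, adjusted p = 5.9e-06), and Sfrp5 (-7.02), Oxtr (-6.68), Edn3 (-6.53), Kctd12b (-6.42), Hapln1 (-6.22) and Wnk3 (-4.90) were among the other largest falls. Pdx1 fell by 3.29 and Ins1 by 0.54 (adjusted p = 0.00016), and Ins2 was at 0.00 (0.97). Sod2 (3.15), Gpx1 (2.10), Hmox1 (3.78), Ddit3 (4.36) and Alox12 (5.05) rose.

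In the presence of ML351, 32 of 32 interferon response genes rose (median 5.23), as did 16 of 16 MHC class I genes (3.36) and 27 of 27 NF-κB targets (3.24). Of 18 chemokines 16 rose and 1 fell (5.31), and of 27 apoptosis genes 21 rose and 2 fell (0.88). These 5 lists were called by camera and held with an estimated correlation (adjusted p = 0.017, 0.008, 0.043, 0.044 and 0.044). Camera also called β-cell (median -1.95), α-cell (-4.45), δ-cell, PP-cell and endothelial (-3.07) genes down, with adjusted p of 0.1, 0.13, 0.11, 0.14 and 0.11 with an estimated correlation. MHC class II (3.89), glycolysis and immediate early genes were called up, with 0.14, 0.26 and 0.14 with an estimated correlation. Antioxidant enzymes, NRF2 targets, NADPH oxidase and macrophage genes were called up, with 0.22, 0.26, 0.096 and 0.14 with an estimated correlation. Cell cycle, cholesterol synthesis and exocytosis genes were called down, with 0.27, 0.26 and 0.14 with an estimated correlation. The eicosanoid list, 11 up and 2 down of 19, was called at 0.037 (adjusted p = 0.22 with an estimated correlation), but not without ML351 replicate 3 (0.055) or combination replicate 4 (0.05, above the threshold before rounding). Of 19 acinar markers 12 rose and 1, Bhlha15 (-2.99), fell over all genes, and 10 and 1 adjusted over the list alone (median 2.80, camera adjusted p = 0.071). Ctrl (3.69) and Rnase1 (2.18) were among those that rose, and the summed acinar CPM was 236, 289 and 105 with ML351 and 1390, 1640 and 1110 with the combination. ER stress genes, 12 up and 12 down, had a median of -0.07 and a mean of 0.45, and camera ranked them up (adjusted p = 0.56). In all, edgeR called 10079 genes (71.5%), 4954 higher and 5125 lower, and the CPM did not overlap for 74% of genes, against 10% by chance. Camera called 21 of 29 lists, 13 up and 8 down, and members were called 441 times both over all genes and adjusted over the list alone.

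Averaged over both backgrounds, macrophage markers were lower with ML351 (3 of 15 over all genes, median -0.40, camera adjusted p = 8.7e-09, and 0.048 with an estimated correlation). Cyp1a1 fell by 2.79 on the log2 scale (SE 0.32, edgeR adjusted p = 0.0084), Clec7a by 0.65 (SE 0.069, adjusted p = 0.00068), the lysosomal glycoprotein gene Gpnmb by 0.59 (SE 0.082, adjusted p = 0.0068), Cda by 0.54 (SE 0.066, adjusted p = 0.0012) and the complement gene C1qc by 0.53 (SE 0.074, adjusted p = 0.0045). These 5 calls held in all 21 alternatives run, with highest adjusted p of 0.0351, 0.0065, 0.0445, 0.00812 and 0.0192. Laptm5 (-0.51), Fcer1g (-0.47) and the microRNA locus Mir6236 (-0.57) completed the largest falls. Nr4a2 (0.65), St7 (0.47), Cxadr (0.47), Malat1 (0.46), Bhlha15 (0.42), Ccdc107 (0.42), Chac2 (0.40) and Igsf5 (0.40) were the largest rises. Of these falls and rises, St7 was lost in 1 of 21 alternatives, Malat1 and Bhlha15 in 3, Ccdc107 in 4, Fcer1g in 5, Laptm5 in 7, Cxadr in 11, Nr4a2 in 13, Mir6236 and Chac2 in 14 and Igsf5 in 16. Nfe2l2 fell (-0.27, SE 0.048, adjusted p = 0.013) and was called in all 21 alternatives (highest 0.0435). Nos2 fell (-0.40, SE 0.09, adjusted p = 0.044), a call lost in 13 of 21 alternatives (adjusted p 0.000234 to 0.15), among them the removal of vehicle replicate 1 or 2, ML351 replicate 1 or 2, any cytokine replicate, or combination replicate 1 or 2. Sod1 (-0.20, adjusted p = 0.047) was lost in 12 alternatives.

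The 3 macrophage markers that fell with ML351 over all genes were C1qc, C1qb (-0.40) and Tyrobp (-0.42), and 9 were called adjusted over the list alone. Of 28 ER stress genes 3 (Hspa5 at 0.26, Pdia4 at 0.20 and Pdia6 at 0.19) rose, and adjusted over the list alone 12 rose and 1 fell (median 0.10, camera adjusted p = 1.7e-05, adjusted p = 0.33 with an estimated correlation). Of 13 AHR and xenobiotic genes 2, Cyp1a1 and the receptor repressor gene Ahrr (-2.73, at most 0.758 CPM in any group), fell, and adjusted over the list alone 7 fell and 1 rose (median -0.12, camera adjusted p = 0.031, adjusted p = 0.33 with an estimated correlation, fry adjusted p = 0.054). Glycolysis (1 fell, 9 adjusted over the list alone, median -0.17, camera adjusted p = 7.5e-06), MHC class II (1 and 4, -0.38, 0.00012), endothelial (0 and 5, -0.33, 0.0021), Schwann cell (0 and 2, -0.60, 0.0054), chemokine (0 and 2, -0.21, 0.031) and MHC class I genes (2 and 3, -0.01, 0.047) were called down. For these 6 lists the adjusted p was 0.33 with an estimated correlation. β-cell genes (0 and 1, median -0.08) were called down at 0.0044, with an adjusted p of 0.43 with an estimated correlation. The AHR and xenobiotic list was not called without vehicle replicate 2 (0.054), ML351 replicate 2 (0.12), cytokine replicate 3 (0.11) or combination replicate 1 (0.083). The chemokine list was not called without vehicle replicate 1 (0.051), ML351 replicate 2 (0.18), cytokine replicate 4 (0.1), combination replicate 1 (0.088) or 4 (0.1), nor with the replicate block (0.07). The MHC class I list was not called without vehicle replicate 1 (0.051) or 2 (0.056), ML351 replicate 2 (0.12), cytokine replicate 3 (0.053) or 4 (0.094), combination replicate 4 (0.11), nor with the block (0.052). Of single list members, Gstp1 (-0.41), Gstm1 (-0.24), Sepp1 (-0.25), Cplx2 (-0.36), Nfkb1 (-0.31) and Gbp2 (-0.29) fell, and Rsad2 (0.35) and Hhex (0.60) rose, with adjusted p from 0.012 to 0.047.

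In all, edgeR called 218 genes for the averaged ML351 effect, 94 higher and 124 lower, while DESeq2 called 576 and limma-voom 130. With DESeq2 size factors the split was 68 higher and 153 lower. The count was 52, 57 and 68 without vehicle replicates 1, 2 and 4, 97 without ML351 replicate 1, 85, 134 and 81 without cytokine replicates 1, 3 and 4, and 115 without combination replicate 2. It was 88 with the replicate block, 83 with the acinar covariate and 42 without both libraries at the ends of the second component. Camera called 10 of 29 lists, 1 up and 9 down, and the macrophage list alone held with an estimated correlation. Fry called the macrophage list (0.0014) and the NADPH oxidase list (0.0064), whose median was -0.16 and mean 0.47. Members were called 24 times over all genes and 84 times adjusted over the list alone. Median, mean and test differed in sign also for eicosanoid (0.01, -0.02, down), NF-κB (0.02, -0.01, down), NRF2 (0.03, 0.13, down), apoptosis (0, 0.04, down) and oxidative phosphorylation genes (0.01, 0, down), all not called.

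The interaction asked whether the cytokine response differed with ML351. Ankrd10 (chromosome 8, 11611583 to 11635757), an ankyrin repeat protein gene, was at 84.5 ± 4.19 CPM with vehicle, 69.5 ± 1.71 with ML351, 30.7 ± 1.16 with cytokines and 38.8 ± 1.82 with the combination (SD, n = 3). It was the 1 gene called by edgeR (0.62, SE 0.089, adjusted p = 0.03), with 1160 genes at an unadjusted p under 0.05. DESeq2, which gave an adjusted p to 3709 genes only, called 58, and limma-voom called 0. The next smallest p-values belonged to Stk38l (0.57, adjusted p = 0.13), Slc40a1 (0.49, 0.17), Plvap (-1.41, 0.18) and Pabpc1 (-0.40, 0.2). The Ankrd10 call was lost in 14 of 21 alternatives (adjusted p 1.25e-06 to 0.343), and edgeR called 0 genes without vehicle replicate 1 or 4, any ML351 replicate, cytokine replicate 1 or 4, or combination replicate 1 or 2. Without cytokine replicate 3 edgeR called 1 other gene. For Cyp1a1 the interaction was -2.72 (adjusted p = 0.37).

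Camera called 7 lists for the interaction, 3 up and 4 down, with 0 members called by edgeR over all genes and 13 adjusted over the list alone, and 0 lists held with an estimated correlation. Acinar markers had a median of 2.18 (camera adjusted p = 3.4e-08, and 0.62 with an estimated correlation), beside the summed acinar CPM of each group given above. Endothelial markers had a median of -1.04 with 7 of 11 lower adjusted over the list alone (3.6e-09, and 0.18 with an estimated correlation, fry 0.036). MHC class II genes (0.55; 0.0087) and ER stress genes (-0.13; 0.00069) both had an adjusted p of 0.62 with an estimated correlation. Glycolysis genes (-0.22, 1 called adjusted over the list alone) had 0.002, and 0.63 with an estimated correlation. Oxidative phosphorylation genes (-0.08) had 0.02, and 0.75 with an estimated correlation. PP-cell genes (0.46, 1 called adjusted over the list alone) had 0.035, and 0.54 with an estimated correlation. Calls without single libraries were lost for glycolysis (0.15 without vehicle replicate 4) and MHC class II genes (0.06 without vehicle replicate 2, 0.071 without combination replicate 2). Oxidative phosphorylation was lost without vehicle replicate 2 (0.21), ML351 replicate 3 (0.16), cytokine replicate 4 (0.19) or combination replicate 2 (0.49), and with the replicate block (0.14). PP-cell genes had 0.076 and 0.075 without vehicle replicates 2 and 4, 0.077 and 0.067 without ML351 replicates 1 and 2, 0.12 without cytokine replicate 1, and 0.079 and 0.071 without combination replicates 1 and 2. Without vehicle replicate 2 or combination replicate 2 camera called 4 lists. Median, mean and test differed in sign for NADPH oxidase (0.07, -0.47, up), AHR and xenobiotic (0.01, -0.08, up), apoptosis (-0.06, 0.05, down), ductal (-0.03, 0.16, up), eicosanoid (-0.08, 0.05, up), β-cell (-0.01, 0, up) and fatty acid synthesis genes (0, 0.10, down), all not called.

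The cytokine responses with and without ML351, which share no library, overlapped in most called genes. Higher in both were 4522 genes and lower in both 4667, against 1750 and 1910 for independent lists of these sizes, and 3 went opposite ways, against 3650. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.95. Among 9102 genes with an average log2 CPM of at least 3, the slope of the response with ML351 on that without was 0.962, and 0.989 (SD 0.0027) over 50 simulated data sets with no ML351 effect, in which genes varied independently. The ML351 effect and the cytokine effect share the cytokine libraries, and their covariance was -0.0304, against -0.00867 (SD 0.003) simulated, a difference of -0.0218 or -1.4% of the variance of the cytokine effect. Of the 202 genes called for the combination against cytokines, 152 (75.2%) had the same sign for ML351 against vehicle, against 58.7% of all genes. The median ratio of their log2 fold changes, without cytokines over with, was 0.21, over genes selected for their change with cytokines. Of the 5 genes called for ML351 against vehicle, 1 higher (Xpo1) and 2 lower (Clec7a and Enpp2) were also called with cytokines, against 0.0129 and 0.0236 for independent lists. All contrasts come from 1 model, in which the groups share the dispersion of a gene. Calls in contrasts without a shared library are thus not independent, and the values for independent lists in this paragraph are a reference and not a test.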

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

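The tests that weigh the acinar pattern were chosen only after that result was seen, while the counts over other divisions of the libraries were set beforehand. Ankrd10 stood out because its cytokine response differed with ML351 by the interaction test of edgeR (0.62 on the log2 scale, adjusted p = 0.03 and 1.25e-06 to 0.343 over 21 alternatives). For 7 lists the cytokine response differed with ML351 by camera's interaction test at a correlation of 0.01, and for 0 of them with an estimated correlation, while fry called 1, the endothelial list. The median interaction was 2.18 for acinar markers and -1.04 for endothelial markers. It was 0.55 for MHC class II genes, 0.46 for PP-cell genes, -0.22 for glycolysis, -0.13 for ER stress and -0.08 for oxidative phosphorylation genes.

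Libraries were also divided in other ways within both backgrounds, 100 divisions being drawn from 200. At least 1 interaction gene was called in 6 of the 100, with up to 25 genes against the real 1, and at least 7 lists were called in 36, with up to 15, so chance is not excluded for either count. What lay behind the 25 genes of the division with the most calls was not traced. It can include the treatment, because exchanging labels in 1 background turns part of an averaged ML351 effect into an apparent interaction.

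Acinar markers had a median log2 change of 1.08 with the combination against cytokines over 18 genes without Bhlha15, the 1 member of the list that edgeR called, and camera's call of the whole list was lost with an estimated correlation (adjusted p = 0.79) and absent in fry (adjusted p = 0.32). Cytokine replicate 1 alone, whose Prss2 level was 6.69 CPM beside 104 and 144 in the other cytokine libraries and 184 to 295 with the combination, may account for part of the change, since the median was 0.50 without it. Exocrine tissue carried over in varying amounts is a candidate explanation: 93% of the within-group variance of these genes lay in 1 component, against a median of 49.8% and a central 95% range ending at 79.3% over 1000 random lists. Random lists hold unrelated genes, and acinar genes regulated together would also share a component, so the share does not favour carry-over over regulation. The SD of the acinar score was 2.44 within the cytokine group and 0.26 within the combination group. The exact two-sided permutation test of the acinar score (difference 2, n = 3 each) gave p = 0.1. That is the smallest value that 3 libraries against 3 allow, so the test could not decide whether the groups differ. An effect of ML351 cannot be told apart from carry-over in any case, because carry-over that differed between the groups would shift the same score. ML351 alone went the other way (median -1.12), a direction that varying carry-over permits and that an effect of ML351 limited to cytokine-treated islets does not exclude.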

How the results depend on the processing

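The acinar covariate and the removal of both libraries at the ends of the second component were chosen after the data were seen, all other alternatives before. The 10209 and 10079 genes called for cytokines without and with ML351 stayed within 1.5 times under every alternative, from 9618 to 10259 and 9448 to 10104 with single libraries left out, and 0 named genes reversed direction. Calls of named genes were lost at least once for 4 of 133 with cytokines against vehicle, 7 of 136 with the combination against ML351, 24 of 26 with the combination against cytokines, 31 of 38 in the averaged contrast, 5 of 5 with ML351 against vehicle and 1 of 1 in the interaction. Dropping the filter on low counts removed no gene and tests nothing.

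The counts of genes for ML351 varied, and the cause was not tested. For ML351 against vehicle, edgeR called 5 genes (1265 at an unadjusted p under 0.05), 0 with DESeq2 size factors, 0 with the acinar covariate, 0 without both libraries at the ends of the second component, 16 with only the groups compared, 110 with DESeq2's Wald test, and 0 to 17 with single libraries left out. For the combination against cytokines it called 202, and 527 with DESeq2, 36 with the acinar covariate, 76 without both libraries, 59 with only the groups compared and 54 to 236 with single libraries left out. For the averaged effect it called 218, and 576 with DESeq2, 130 with limma-voom, 83 with the acinar covariate, 42 without both libraries and 52 to 270 with single libraries left out. For the interaction it called 1, and 58 with DESeq2, 0 with limma-voom, 0 with the acinar covariate, 0 without both libraries and 0 to 1 with single libraries left out.

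Camera's lists depended on the correlation. With an estimated correlation the number called went from 20 to 3 for cytokines against vehicle, 9 to 1 for ML351 against vehicle, 6 to 0 for the combination against cytokines, 21 to 5 for the combination against ML351, 10 to 1 in the averaged contrast and 7 to 0 in the interaction. Fry, which asks another question, called more lists than camera for cytokines against vehicle and the combination against ML351, 26 in each, and fewer in the other contrasts, with 5 for ML351 against vehicle, 2 for the combination against cytokines, 2 in the averaged contrast and 1 in the interaction. With single libraries left out camera called 6 to 11 lists for the combination against cytokines and 4 to 8 for the interaction.

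Replicate numbers are shared between groups but did not pair the libraries: of 13 pairs with the same number 2 correlated above 0.1, the median was -0.07 against 0.02 for other numbers, and 3 of 12 libraries correlated best with their own number. With the replicate block the counts of genes were 9699 and 9622 for cytokines without and with ML351, 0 for ML351 against vehicle, 53 for the combination against cytokines, 88 for the averaged effect and 0 for the interaction. Camera called 19, 10, 6, 21, 9 and 6 lists with the replicate block, in the order of contrasts given for the estimated correlation. Depth limits the genes under about 1 CPM, such as Cyp1a1 with the combination and Ahrr.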

Other observations

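Gene lists and tests described here were chosen after the results were seen, except the hypoxia test of glycolysis genes and the counts over other divisions of the libraries, which were set beforehand. Npas4, an activity-dependent transcription factor, rose from 0.103 CPM with cytokines to 2.9 CPM with the combination (log2 fold change 4.70, SE 0.76, edgeR adjusted p = 0.0097, n = 3). Nr4a1 (1.58) and Nr4a2 (0.91) rose as well, calls that were lost in 9 and 14 of 22 alternatives. Other genes induced by stimulation were not called, with Fos at 0.94 (adjusted p = 0.26), Egr1 at 0.03 (0.97), Junb at -0.11 (0.76) and Arc at -0.47 (0.34). These 7 genes were picked with the rises of Nr4a1 and Nr4a2 in view, so they are not tested as a group. With cytokines alone Nr4a2 had fallen (-2.54), while Junb (2.66), Arc (1.10), Fos (1.02) and Egr1 (0.91) rose.

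Of 16 circadian clock genes 4 rose and 8 fell with cytokines, a contrast in which edgeR called 72.5% of all genes. Nr1d1 (2.24) and Per1 (1.60) rose, and Per3 (-1.97), Arntl (-0.81) and Clock (-0.68) fell. By fry the clock list had no shared direction (unadjusted p = 0.52), so these counts do not set clock genes apart from other genes. In the averaged ML351 contrast of edgeR, Nr1d1 fell (-0.32, adjusted p = 0.0086) and Clock rose (0.23, adjusted p = 0.046), with a list median of -0.03 (95% bootstrap interval -0.12 to 0.08). Bootstrap intervals, here and below, resample the genes of a list and not the libraries, so they do not measure the spread between libraries. Of 18 hypoxia target genes 10 rose and 2 fell with cytokines (median 1.04, 95% bootstrap interval -0.01 to 1.69). Among the risen ones were Adm (4.65), Egln3 (3.20) and P4ha1 (1.73). Limma's fry gave the direction of the 18 an adjusted p of 8.2e-05 over the 4 lists chosen. Fry called 26 of the 29 fixed lists in this contrast, so that value does not set the hypoxia targets apart from other genes. Lower with the combination than with cytokines, each at an adjusted p of 0.0087, were the hypoxia targets Egln1 (-0.44) and Ndrg1 (-0.43), which are not among the 18 because their calls had been seen, and the endothelial gene Vwf (-4.00, 0.858 to 0.0473 CPM).

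Of 19 glycolysis genes 2 fell with the combination against cytokines (median -0.28), and camera's call of the list was lost with an estimated correlation (adjusted p = 0.60) and absent in fry (adjusted p = 0.13), so the pattern itself is not firm. Lower expression of hypoxia target genes was tested as a hypothesis that could connect them. The 18 hypoxia targets, without Egln1 and Ndrg1, had a median of -0.19 (95% bootstrap interval -0.30 to -0.03), 14 of 18 were below 0, and fry's unadjusted value for their direction was 0.085, so the criterion set beforehand was missed. That criterion also took any p above the threshold as evidence against the hypothesis, which was wrong, because a missed threshold excludes nothing. The interval below 0 resamples genes and not libraries, so it does not make up for the missed criterion. The hypothesis has no support from this test, and the question stays open. In the averaged contrast, looked at afterwards, the median was -0.12 (-0.23 to -0.06, fry adjusted p = 0.046 over 4 lists), and Ankrd37 (-0.54, adjusted p = 0.027) and P4ha2 (-0.31, adjusted p = 0.019) fell. The averaged contrast includes the same cytokine and combination libraries and is not a separate test of the hypothesis.

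Cyp1a1 was lower with ML351 in every library of both backgrounds, at 6.97, 11.8 and 7.87 CPM against 21.1, 22 and 28.6 with vehicle, and at 0.293, 1.59 and 0.363 CPM with the combination against 10.1, 13 and 18.7 with cytokines. A single library is excluded as the cause, since the averaged log2 change stayed between -3.41 and -2.61 with any 1 library left out. With ML351 alone the endothelial list showed no fall, at a median of 0.28 (0.05 to 0.32 over genes, fry adjusted p = 0.64). This argues against fewer endothelial cells there, though the interval does not measure the spread between libraries. With cytokines the median was -0.69 (-1.15 to -0.43 over genes) beside a Cyp1a1 change of -4.15. These values argue against an even loss of endothelial cells as the whole cause. A part of that change, or loss of a subset of these cells, stays open. Vwf, an endothelial gene not on the list, fell by 4.00, but it was picked after its call was seen. Its fall is weak evidence, as it rests on the few counts behind the low CPM given above. Lower activity of the aryl hydrocarbon receptor, which induces Cyp1a1, remains a hypothesis: the other 6 receptor targets had a median of -0.26 in the averaged contrast with an interval that holds 0 (-2.34 to 0.43), though 5 of 6 were below 0 and fry, on this list chosen when the fall of Ahrr was known, gave adjusted p = 0.0016 over 4 lists (0.011 for ML351 alone and 0.018 for the combination against cytokines). Direct action of the compound on the receptor was not tested.

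The largest rises with cytokines ended at nearly the same fold. Among 1559 genes of at least 100 CPM with cytokines, the 10 lowest vehicle levels were 0.279% to 0.359% of the cytokine level, a spread of 1.29-fold, against 1.77-fold for ML351 and the combination, and 3.08-fold and 2.82-fold for falls; at 20 CPM or more the spreads of the rises were 1.73-fold and 2.12-fold, with lowest shares of 0.193% and 0.13% that rest on 3 and 2 counts. The prior count of the fit is excluded, because ratios of mean CPM were 1.03 times the fitted folds. Reads carried between libraries sequenced together could give such a floor, and at 20 CPM or more the falls of Sfrp5 (0.321%) and Edn3 (0.364%) ended at like shares, but the lower shares of the ML351 group (0.197% at 100 CPM or more), its spread past 2-fold at 20 CPM or more and low basal expression leave the question open. If reads were carried over, log2 rises of about 8 would be lower bounds.

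Counts of calls were compared with those from other divisions of the same libraries. For the averaged ML351 effect 1 of 100 drawn divisions, the real one, called as many as 218 genes, and the highest other called 14. A chance division of the libraries is thus unlikely to give that count. Such divisions do not test whether the libraries of a group share more than their treatment. For its lists 6 of 100 called at least the real 10, with 15 as the highest other, so chance is not excluded. Comparisons of 3 libraries with 3 have 10 divisions, too few for a share under 0.05. There, 1 division reached the real count of genes for cytokines against vehicle (10209, highest other 0), 2 for ML351 against vehicle (5, 12), 1 for the combination against cytokines (202, 2) and 1 for the combination against ML351 (10079, 0). For lists, 1 division reached the real count for cytokines against vehicle (20, 19), 1 for ML351 against vehicle (9, 8), 4 for the combination against cytokines (6, 12) and 3 for the combination against ML351 (21, 25). What lay behind the 12 genes called in another division of the vehicle and ML351 libraries was not tested, and chance is not excluded for them.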
